A study of Homo sapiens with 2 samples.

How the data were processed

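Expression was measured with 2 biotin-labelled Affymetrix arrays, 1 of total RNA from 786-O cells and 1 from cells of a line derived from them that holds a working VHL gene, called the VHL-restored line. Total RNA was extracted with Trizol per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, as their range shows. R 2.10 is the only tool named in the submitters' processing notes, and the background correction, normalization and probe summary that made the deposited intensities are not given in the sources used here. Any such step could compress or shift differences between the arrays, and its effect cannot be separated from the values.

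Each array gave 54613 probe sets, with quartiles of 9.97 and 109 in 786-O and 10.1 and 105 in the VHL-restored line. Over all probe sets of the 2 arrays the log2 values had a Pearson r of 0.982 and a Spearman rho of 0.978, across probe sets, which are not independent replicates. A platform annotation paired 41091 probe sets with a single gene, 1801 with several genes and left 11721 unnamed here. Current symbols were taken by Entrez gene number for 41037 of the single-gene probe sets. Probe sets with several genes or none were not used for genes. The planned comparison of 3 prime and 5 prime control probe sets, a check of RNA quality, was not run because the table used here holds 0 control probe sets of that kind. RNA quality was therefore not analysed here.

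Intensities were taken as log2(value + 16). A gene was represented by its single-gene probe set with the highest mean over both arrays, and counted as measured where the higher value exceeded the pooled median of all values, an intensity of 22.3. The median difference of the 13291 measured genes was 0.05 and its SD 0.45, and 6484 genes were below the floor on that probe set, 7 of them with another probe set above it. With 1 array per group no test, standard error or p-value was possible, and genes were described by fixed sizes, at least 2-fold and at least 4-fold. Lower bounds of folds, added after the data were seen, set the array below the floor to the floor with the same pseudocount. For each of 25 gene lists, the median difference of measured members was placed among the medians of 10000 random lists of equal size, drawn with replacement within 10 bins of mean expression. A list is said to stand apart when its median lies outside the central 95% of these. The percentile describes these 2 arrays and carries no information on spread between cultures.

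The size rules, the lists, the naming rule and the alternatives marked as planned were fixed before the data were examined. The naming rule took VHL, EPAS1, HIF1A and VCAM1, then the 12 highest and 12 lowest measured genes whose other probe sets above the floor differed the same way by at least 0.58, then up to 4 members of each list with the largest difference. Further genes named in the text were chosen after their values were seen. XIST and Y-linked genes were left out of the named genes.

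Alternatives were quantile normalization of the 2 columns, removal of the intensity-dependent trend, no filter on low values, a floor at the 75th percentile, the median over probe sets of a gene, only probe sets without the suffixes _s_at, _x_at and _a_at, pseudocounts of 1 and 64, and a threshold of 1.5-fold. For runs of neighbouring genes, 13253 measured genes were ordered by the GRCh38.p14 annotation, used for gene order only. Running medians over 31 genes were compared with the 95th percentile of the highest running medians, and the matching lower limit, in 100 shuffles of gene order. Genes within any window past those limits are called members of shifted runs. After the runs were seen, the number of genes past the limits was also compared with that in 100 shuffles of gene order, with and without the intensity trend.

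The procedure was tested on simulated data with 13291 genes at the real levels, with noise from the spread between probe sets, so array and culture noise were not simulated. Planted log2 changes of 1.5 passed 2-fold in 86% of genes when upward and 68% when downward, and planted changes of 3 in 100% and 96%. Of unchanged genes 0.0995% passed 2-fold, a 30-gene list shifted by 0.5 lay at percentile 100, and 1 of 100 unchanged lists lay outside the central range. The noise was normal and of the same size for all genes. The share of unchanged genes past 2-fold follows from that setting and does not estimate the share in the real data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.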

Results

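Total RNA from 2 human renal cell carcinoma lines was labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per line. 786-O is a clear-cell kidney cancer line that carries a mutated VHL gene, and the other line, derived from it, holds a working copy and is called the VHL-restored line here. Each array gave an intensity in arbitrary units for 54613 probe sets, with a median of 21.97 in 786-O and 22.58 in the VHL-restored line and maxima of 18757 and 18227. Probe sets naming a single gene covered 19775 genes, of which 13291 had their representing probe set, the one with the highest mean, above the floor of 22.3 on at least 1 array and are called measured. With 1 array per line there was no replicate check of any difference, and the number of arrays limits the precision of every value. Differences are log2(VHL-restored + 16) minus log2(786-O + 16), so a positive value is higher on the array labelled as the VHL-restored line, and folds are on that scale, which understates differences of dim genes.

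The comparison addressed which genes depend on a working VHL, the substrate-recognition part of a ubiquitin ligase that marks HIF alpha subunits for destruction. VHL itself had an intensity of 28.85 in 786-O and 15.96 in the VHL-restored line on its brighter probe set, the latter below the floor, and 6.32 and 7.96 on the other, below the floor. These probe sets did not check the labels, because they lay near or below the floor and a probe outside the introduced sequence would not detect it, so every direction given here rests on the array labels alone. EPAS1, which encodes HIF-2 alpha, was 2.13-fold higher on the array labelled as the VHL-restored line, at 799 against 367. A second EPAS1 probe set differed by 0.42 and the other lay below the floor. HIF1A was below the floor on both arrays, at 6.37 and 5.69. VCAM1, an adhesion molecule for leukocytes, was 3.68-fold higher on the array labelled as the VHL-restored line, at 876 against 226.

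The largest difference was in LCN2, which encodes the iron-trafficking protein lipocalin-2 and was 41.4-fold lower on the array labelled as the VHL-restored line, at 27.9 against 1800. The complement component C3 was 8.66-fold lower there, the actin-bundling protein gene LCP1 11.3-fold lower and ALOX5AP, needed for leukotriene synthesis, 6.13-fold lower. In the other direction, the aldo-keto reductase gene AKR1B10 was 17.8-fold higher, at 5102 against 272, and the calcium-binding protein gene S100A2 13.8-fold higher, at 5461 against 379. GJA1, which encodes the gap junction protein connexin 43, was at least 6.95-fold higher, and the tight junction gene CLDN16 8.64-fold higher. In all, 495 measured genes (3.72%) were at least 2-fold apart, 205 higher and 290 lower on the array labelled as the VHL-restored line, and 73 were at least 4-fold apart, 29 higher and 44 lower. Where a gene was below the floor on 1 array its difference depends on the pseudocount, and its fold is given as a lower bound with that array at the floor. This held for 77 of the 495 genes, and 473 of the 495 were at least 2-fold apart by that bound.

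The other genes named by the rule for the 12 highest were AKR1C3, NDN, ADGRE1, AKR1C2, LAPTM5, AKR1C1, PDZK1 and DDIT4, with log2 differences from 3.57 for AKR1C3 to 2.63 for DDIT4. NDN and ADGRE1 were below the floor in 786-O, and were at least 9.24-fold and at least 6.89-fold higher. AKR1C1, AKR1C2 and AKR1C3 are near-identical paralogs, and their probe sets may not tell them apart, so the individual values are uncertain. The other genes of the 12 lowest were RBM23, HNRNPL, RBM24, SLCO1B3, RAB31, NPPB, ADAMTS5 and CNTN1. The RNA-binding protein gene RBM23 had a difference of -3.53, and HNRNPL, a splicing regulator, differed by -3.006 and -3.001 on its 2 probe sets. NPPB, which encodes a natriuretic peptide, was 6.70-fold lower, and ADAMTS5, which encodes an aggrecan-cleaving protease, at least 5.01-fold lower. RBM24, SLCO1B3, RAB31 and CNTN1 were below the floor in the VHL-restored line, with lower bounds from 5.01-fold for RAB31 to 5.97-fold for CNTN1. LAPTM5, SLCO1B3 and RAB31 lay in runs of neighbouring genes that were shifted together.

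**Figure D1:**
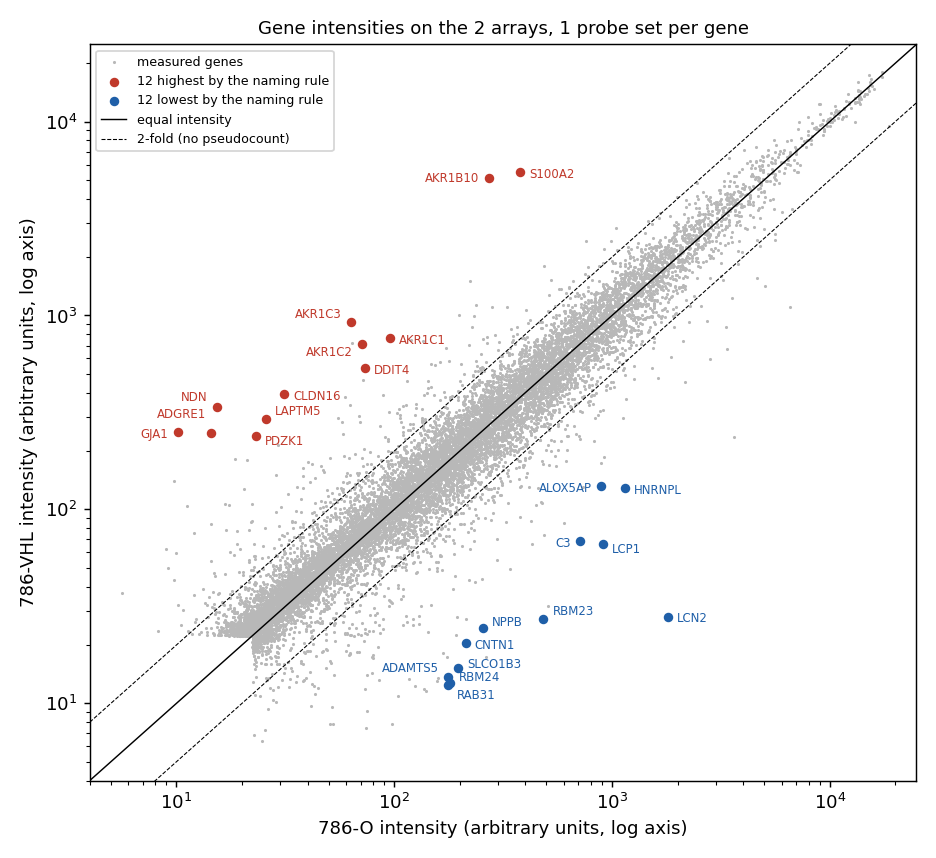
Intensity of each measured gene on the array of 786-O (horizontal) and that of the VHL-restored line (vertical), in arbitrary units on log axes, 1 point per gene, with the 12 highest (red) and 12 lowest (blue) genes by the naming rule. Most genes lie near the line of equal intensity, while LCN2 stands at 1800 in 786-O against 27.9 and AKR1B10 at 272 against 5102. With the pseudocount, which the axes do not use, 87.2% of measured genes were within 1.5-fold.

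The spread between probe sets of a gene was the only measure of error. Over 6436 genes with several probe sets above the floor, its SD was 0.315 log2 units, which covers differences between probes and not between cultures or arrays. Of 271 such genes at least 2-fold apart, 135 (49.8%) had other probe sets differing the same way by at least 0.58, and 109 of 142 (76.8%) did with the floor at the 75th percentile. The counts of genes also depended on the pseudocount, and 686 genes were at least 2-fold apart with a pseudocount of 1 and 256 with a pseudocount of 64.

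HIF targets of VHL-defective renal cells went both ways. Of 35 measured members, CA12, DDIT4, NDRG1 and PFKFB4 were at least 2-fold higher on the array labelled as the VHL-restored line and LOX and ADM at least 2-fold lower. The stress-response gene DDIT4 differed by 2.63, NDRG1 by 1.74 and ADM, which encodes the vasodilator adrenomedullin, by -1.51, and the collagen cross-linking enzyme gene LOX was at least 2.35-fold lower, with a probe set at -0.64. The carbonic anhydrase gene CA12 was 9.15-fold higher, with 5 probe sets from 3.19 to 4.13 and the other at 0.03. VEGFA, CCND1, TGFA and SLC2A1, named after their values were seen, differed by 0.05, 0.14, 0.00 and 0.62, but the other CCND1 probe set differed by -0.87, and probe sets of VEGFA and TGFA reached 0.52 and 0.35. The median of the list was 0.10, at percentile 76.8 of 10000 random lists of equal size matched on mean expression. PFKFB4, ADM and SLC2A1 lay in shifted runs of neighbours.

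Among 26 glycolytic and HIF-1-type genes, only the enolase gene ENO2 was at least 2-fold apart, with a difference of -1.27. The phosphofructokinase gene PFKL differed by -0.85, PGAM1 by 0.53 and PKM by 0.42, and the list median of 0.06 lay at percentile 46.7. In the VHL complex and HIF machinery, EPAS1 alone of 13 members was at least 2-fold apart, ARNT2 differed by 0.94 and the median was 0.06, at percentile 52.8.

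Interferon-stimulated genes were higher on the array labelled as the VHL-restored line. Of 35 measured members 31 were higher and 4 lower, and 8 were at least 2-fold higher with none 2-fold lower. IFI44 differed by 2.45, the ubiquitin-like modifier gene ISG15 by 1.71 and the antiviral gene IFIT2 by 1.51, and IFI44L was at least 3.14-fold higher. The median of 0.40 lay above those of all 10000 random lists. IFI44 and IFI44L lay in a shifted run of neighbours, and with a pseudocount of 64 the number at least 2-fold higher was 4. Among 19 genes of RNA virus sensing and interferon induction none was at least 2-fold apart. TLR3, a sensor of double-stranded RNA, was below the floor in 786-O and at least 1.27-fold higher, IFIH1, a cytoplasmic sensor of picornavirus RNA, differed by 0.30, and the median was 0.01, at percentile 38.5.

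NF-kB targets were lower on the array labelled as the VHL-restored line in 20 of 33 measured members and higher in 12. The 8 at least 2-fold lower were TNFAIP6, CXCL1, CXCL2, CXCL8, BIRC2, TNF, TNFAIP3 and CXCL3, and VCAM1 alone was at least 2-fold higher. With a pseudocount of 64, 5 were at least 2-fold lower. TNFAIP6 was at least 4.56-fold lower, and the neutrophil chemokine genes CXCL1 and CXCL2 differed by -2.21 and -1.64. The list median of -0.17 lay at percentile 0.13. Without probe sets whose names end in _s_at, _x_at or _a_at, 18 members were left, their median was -0.051 and its percentile 16.1, so the list no longer stood apart, and BIRC2 lay in a shifted run of neighbours. Of 19 NF-kB signalling components, TNFAIP3 alone was at least 2-fold apart, at -1.09. NFKBIB differed by -0.40 and TNFRSF1A by 0.49, and the median was -0.10, at percentile 7.14.

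NRF2 targets, which serve antioxidant defence and detoxification, had the largest list median, 0.67, above those of all random lists. Of 20 measured members 18 were higher on the array labelled as the VHL-restored line and 8 at least 2-fold higher (6 with a pseudocount of 64), among them AKR1B10, the 3 uncertain AKR1C paralogs, the haem oxygenase gene HMOX1 at 2.02 and the cystine transporter gene SLC7A11 at 1.05. Targets of the unfolded protein response and ATF4 had a median of 0.40, also above all random lists, with 6 of 24 at least 2-fold higher and none lower, though 4 with the intensity trend removed and 3 with a pseudocount of 64 or without suffixed probe sets. The asparagine synthetase gene ASNS differed by 2.18, the serine synthesis gene PSPH by 2.13, SESN2 by 1.56, with another probe set at 0.20, and TRIB3 by 1.06. PSPH and SESN2 lay in shifted runs of neighbours.

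Cell cycle genes divided by phase. Of 31 genes of G2 and M phase 27 were lower on the array labelled as the VHL-restored line, and their median of -0.37 lay below those of all random lists. UBE2C, which acts in the destruction of mitotic cyclins, differed by -1.09, CDK1 by -0.83, CENPE by -0.79 and PLK1 by -0.77. The 4 probe sets of CDK1 ranged from -0.83 to -0.15 and the 4 of MKI67 from -0.38 to 0.19. Of 25 genes of G1 and S phase 17 were higher, with CCNE2 at 1.38, the replicative helicase gene MCM6 at 1.02 and CDC6 at 0.89, and their median of 0.27 lay at percentile 99.4. That call ended under 2 of 8 alternatives, where the lowest percentile was 92.5.

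Nuclear-encoded genes of oxidative phosphorylation had small differences in 1 direction, 24 of 28 being higher on the array labelled as the VHL-restored line and none 2-fold apart. ATP5MC1 differed by 0.65 and UQCRB by 0.56, and the median of 0.24 lay at percentile 98.1. That call ended under 2 of 8 alternatives, where the lowest percentile was 80.7, and without members in shifted runs, where it was 96.9. The cholesterol synthesis median was 0.18, at percentile 91.0, with SQLE at 0.67 and EBP at 1.51, though probe sets of SQLE ranged from -0.10 to 0.91 and those of EBP from 0.04 to 1.51. Over the median of probe sets the percentile was 72.7 and no member was 2-fold apart. Fatty acid genes had a median of 0.03, at percentile 43.2, with the desaturase gene SCD at 0.93, and of 0.16, at percentile 82.6, with the floor at the 75th percentile.

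**Figure D2:**
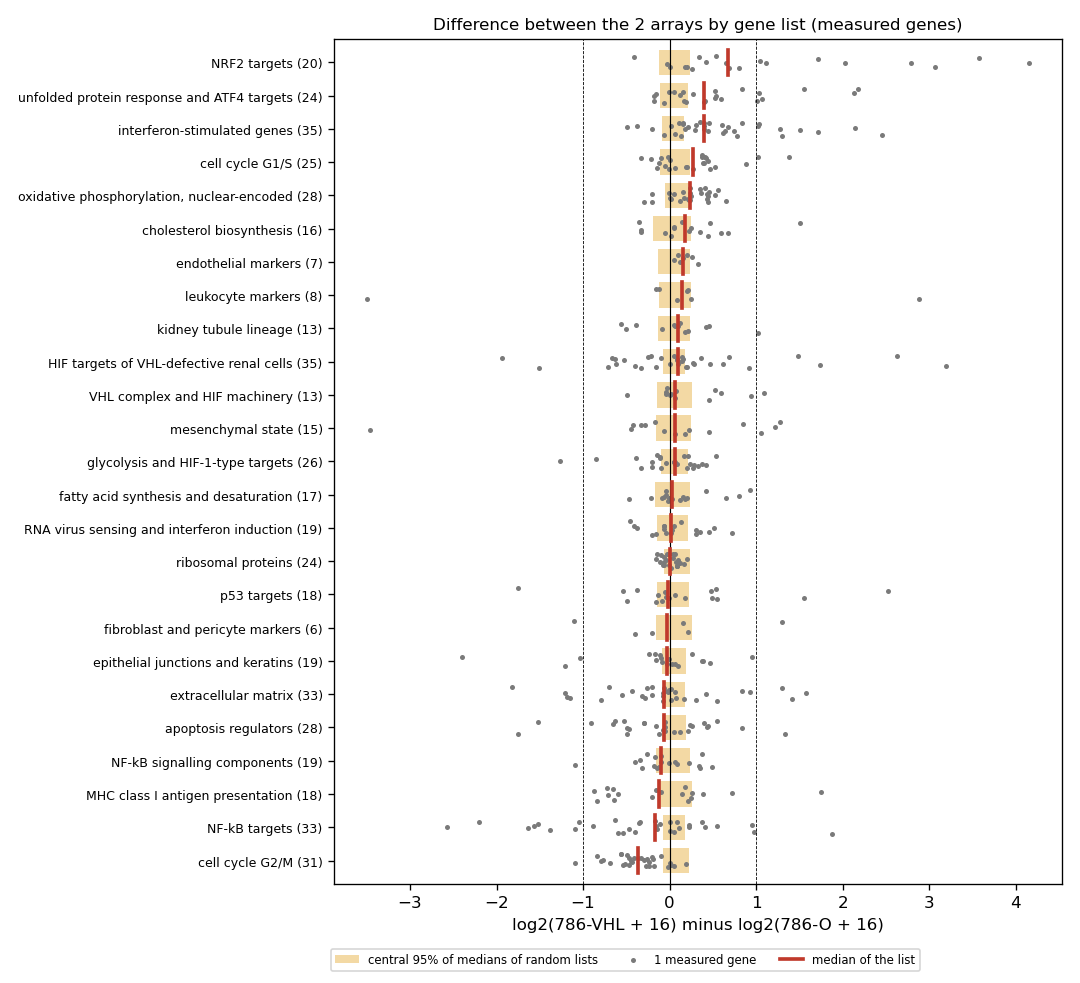
Log2 difference between the arrays of the VHL-restored line and 786-O (positive when higher in the former) of each measured gene (grey points) in the 25 preset lists, with the number of measured genes in brackets, the list median (red line), and the central 95% of medians of 10000 matched random lists (shaded). The medians of NRF2 targets (0.67), ATF4 targets and interferon-stimulated genes (0.40 each) lie to the right of the shading and that of G2 and M phase genes (-0.37) to its left.

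MHC class I antigen presentation had a median of -0.13, at percentile 2.62, just inside the central range, and it lay outside that range under 5 of 8 alternatives, with percentiles from 1.29 to 43.5. HLA-B differed by -0.84 and the peptide-trimming enzyme gene ERAP1 by -0.87, with another ERAP1 probe set at -0.07, whereas the immunoproteasome gene PSMB9 differed by 1.75. HLA genes are near-identical to one another and their individual values are uncertain. Apoptosis regulators had a median of -0.07, at percentile 3.98, and stood apart under 2 of 8 alternatives, with percentiles from 1.90 to 12.9. BAX differed by -1.75 and BIRC2 by -1.52, and the pro-apoptotic gene BIK was at least 2.47-fold higher. The p53 target list had a median of -0.02, at percentile 23.5, with GDF15 at least 5.19-fold higher, SESN2 at 1.56 and BAX at -1.75.

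Extracellular matrix genes went both ways, 3 of 33 at least 2-fold higher and 4 lower, with a median of -0.06 at percentile 3.21, and the list stood apart under 4 of 8 alternatives, with percentiles from 0.97 to 6.41. THBS1, which encodes the angiogenesis inhibitor thrombospondin-1, differed by -1.82, with probe sets from -2.39 to -0.47, and COL6A3 by 1.42. LUM, below the floor in 786-O, was 1 of the 3 counted as higher, but by its lower bound it was only at least 1.39-fold higher. COL6A1 differed by 1.57, but by -0.29 without the _s_at, _x_at and _a_at probe sets. Of the mesenchymal list, 3 of 15 were at least 2-fold higher, among them TGFBR2 at 1.28 and ITGB3 at 1.22, its probe sets ranging from 0.45 to 1.22, and the median was 0.06, at percentile 52.5. That median was -0.12 with the floor at the 75th percentile, at percentile 9.85, and 0.17 without the suffixed probe sets, at percentile 86.7. TAGLN, an actin-binding protein gene, differed by -3.46, but by 0.10 on the probe set left without those suffixes, and lay in a shifted run. Of 19 epithelial genes MAL at -2.40 and DSC2 at -1.20 were at least 2-fold lower, PKP2, below the floor in the VHL-restored line, was at least 1.75-fold lower but its other probe set differed by 0.16, and the median was -0.03, at percentile 9.46. The kidney tubule median was 0.10, at percentile 66.0, with the aminopeptidase gene ANPEP at 1.02, and depended on the setting, from 0.02 over the median of probe sets, at percentile 32.6, to 0.42 over 5 members with the floor at the 75th percentile, at percentile 96.8.

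Markers of other cell types did not stand apart as lists, except that fibroblast and pericyte markers did so without their member in a shifted run, with a median of -0.21 over 5 members at percentile 1.76, a setting chosen after the data were seen. The leukocyte median over 8 measured markers was 0.14, at percentile 81.4, with LCP1 at -3.49 and LAPTM5 at 2.88, and -0.02 at percentile 18.5 without members in shifted runs. The endothelial median over 7 was 0.16, at percentile 85.9, and no marker, VWF included, was 2-fold apart. The fibroblast and pericyte median over 6 was -0.03, at percentile 17.9, with LUM at least 1.39-fold higher and PDPN at least 2.02-fold lower. Ribosomal protein genes, a housekeeping comparison, had a median of 0.01 over 24 members, at percentile 15.7, and none was 2-fold apart. In all, 7 of the 25 lists lay outside the central 95% of random lists, 5 above and 2 below.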

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

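The lists without members of shifted runs and the NF-kB list without CXCL genes were tests chosen after the data were seen. No paired analysis was possible because each line had 1 array, and for that reason no replicate could be left out and no other split of the samples made. Over 196 planned list values 168 moved by less than the spread of random lists, 28 by more and none of the called lists changed sign. G2 and M phase, NRF2, ATF4 and interferon lists stood apart in 8 of 8 alternatives and NF-kB targets in 7; MHC class I, matrix and apoptosis lists, inside the range in the main setting, stood apart in 5, 4 and 2. Of 483 alternative values of 64 named genes at least 2-fold apart, 481 kept their sign and 458 were still 2-fold. Without _s_at, _x_at and _a_at probe sets COL6A1 was at -0.29 and TAGLN at 0.10, 18 genes were at least 4-fold higher and the NF-kB median was -0.051, with fewer genes and probe sets used. It was -0.34 with the floor at the 75th percentile, where probe sets of a gene gave 76.8% agreement, -0.31 over the median of probe sets, -0.16 without run members and -0.15 without CXCL genes. The interferon median was 0.29 without a filter, 0.47 with a pseudocount of 1 and 0.32 with 64. A pseudocount of 1 gave 119 genes at least 4-fold apart (47 higher, 72 lower). A pseudocount of 64, which shrinks dim genes, gave 256 at least 2-fold (110 and 146) and 30 at least 4-fold (14 and 16). The 1.5-fold threshold gave 1702 (831 and 871). Causes were otherwise not tested. Leukocyte, endothelial and fibroblast lists gave no value with the floor at the 75th percentile, nor fibroblasts without the suffixes. Signal over background set the limit for 6484 genes, whose representing probe set was below the floor on both arrays.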

Other observations

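The tests of MALAT1's neighbours, of swapped labels and all tests of runs of neighbouring genes were chosen only after the pattern was seen. Some single genes outside the naming rule were picked after their values were seen, and no group of genes was tested with them. On the array labelled as the VHL-restored line EDN1, which encodes the vasoconstrictor endothelin-1, had an intensity of 66.0 against 429 in 786-O, a log2 difference of -2.44, and its 2 probe sets ranged from -2.44 to -1.79. IGFBP7, an insulin-like growth factor binding protein gene, differed by -2.30 and the growth factor gene FGF5 by -2.45. In the other direction TIMP4, an inhibitor of matrix metalloproteinases, was at least 4.06-fold higher, the basement membrane gene NID2 differed by 2.40, and GAL3ST1, which makes sulfated glycolipids, by 2.25. None of these differences has a replicate.

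HIF targets went both ways, where the function of VHL would predict lower values in the VHL-restored line. Over 8 other settings of probe choice and scaling the lowest percentile of the list median was 56.8, far from the low end. By the rule set beforehand this argued against both, for those settings only. The test was weak, because random lists are rescaled along with the list, and DDIT4 and NDRG1 each had 1 probe set above the floor. The normalization behind the deposited values was not tested and stays open. Swapped array labels cannot be told apart from correct ones, because the median's percentile of 76.8 is inside the range of random lists and the VHL probe sets lie near the floor. Other open explanations, untested here, include culture differences, loss of the introduced gene's function and effects on protein that arrays do not measure.

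MALAT1, a nuclear long noncoding RNA, was lower on the array labelled as the VHL-restored line on 12 probe sets, from -4.18 to -0.90, and HNRNPL on 2. Some MALAT1 probe sets, that at -4.18 included with an intensity of 20.2, were below the floor in the VHL-restored line. The size of those differences depends on the pseudocount. Less nuclear-retained RNA in that sample was argued against, since 22 other such RNAs had a median of 0.16 (95% interval over genes -0.02 to 0.25). A shift shared by the 40 nearest measured genes was set to need a median of -0.5 or lower. It was argued against for HNRNPL by their median of -0.18 (-0.22 to 0.00), which lies above the bound of -0.25. For MALAT1 the median was -0.052 (-0.26 to 0.05), and the interval just missed that bound, so by its own rule the test was undecided. The interval does exclude -0.5, a reading made after the value was seen. Neither median can exclude a change that covers fewer genes. Variation between cultures or clones stays open, and no biological explanation was tested.

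Runs of neighbouring genes were shifted together. Several separate higher runs lay from CHD5 to NEGR1 (499 genes, median 0.26), where the running median was not past the upper limit at 332 genes. Several separate lower runs lay from USP35 to TRIM29 (159 genes, median -0.36), where it was not past the lower limit at 41. Windows of runs held 15.0% of the genes at least 2-fold apart and 9.33% of all. Those windows were picked on the same differences, so this excess is partly built in. Chance order and an intensity trend, as causes of the runs as a whole, were argued against by the scan: 429 genes lay past its limits, and 322 with the trend removed, while 0 of 100 shuffles of gene order gave as many in either case (at most 10 and 14). Runs found on alternate genes were also tested on the genes between them, first with 15-gene windows (29 genes) and then with 31-gene windows chosen after that result, and these shifted by 0.24 (0.06 to 0.47) and 0.29 (0.21 to 0.40), and with the trend removed by 0.28 (0.12 to 0.34) and 0.28 (0.22 to 0.36); the intervals of the first reached below the bound of 0.2 set for them, so that test alone left both open. A candidate explanation is a difference in DNA copy number between the lines. For it, 133 genes from CHD5 to NEGR1 outside every window had a shift of 0.13 (0.08 to 0.17). That passed the bound for this test, which was set after the runs were seen and is lower than the 0.2 used for bright and dim genes. The interval lies wholly below 0.2, but leaving out every window removed the most shifted neighbours, which partly builds in a small shift. This result therefore does not decide for or against copy number. No gene from USP35 to TRIM29 was left to test. The dimmer held-out genes shifted by 0.048 (-0.047 to 0.52), beside 0.32 in the brighter, and with the trend removed by 0.20 (0.02 to 0.34), beside 0.31. With the wider windows they shifted by 0.13 (0.06 to 0.19) and, with the trend removed, by 0.085 (0.01 to 0.20), beside 0.49 and 0.44. Only the third of these intervals excludes the 0.2 that copy number was set to need. The pseudocount also shrinks shifts of dim genes, and the dimmer genes had median intensities from 58.3 to 107. Their small shifts therefore cannot by themselves weigh against copy number. Copy number stays open, as do neighbours regulated together, and no DNA was measured.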
